A study of Arabidopsis thaliana with 4 samples.

How the data were processed

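RNA abundance was measured on 4 Affymetrix ATH1 arrays of Arabidopsis thaliana, Wassilewskija-2 background. The samples were whole plants grown on plates for 10 days at 24 °C under continuous light, after 4 days of stratification at 4 °C, per the labels. There were 2 arrays of wild type plants and 2 of plants that express CBF2 from the 35S promoter, here called 35S::CBF2. The labels give both 35S::CBF2 samples the same replicate number, so they were numbered 1 and 2 in their listed order. Their titles carry the codes E24 and E2, while the protocol text of both names E2, and the labels do not settle whether these are different transgenic lines. The labels do not say that the samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

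The deposited values are signal intensity on a linear scale, 1 value per probe set and array. They were made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. The 2%-trimmed mean over all probe sets was 100.0 on every array, so the values had been scaled to a common mean before deposit and were used without further scaling. Detection calls were not used here. No value column of the table was left unused. No 2 arrays shared an identical value for any probe set.

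The table holds 22810 probe sets, of which 64 are controls and were left out of the tests. Gene names came from a 2016 platform annotation, updated through gene identifiers with the RefSeq gene table of assembly TAIR10.1. In it 13513 probe sets carry exactly 1 gene, 503 carry several genes and 8730 are not listed. Of the probe sets with 1 gene, 13436 matched the gene table and 77 kept the name of the platform annotation. Probe sets without exactly 1 gene were tested and are counted, but not named. Coordinates were not used here, since the build behind the array design is not given in the sources used here; the gene table served for names and for which genes neighbour each other.

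Signals were taken to log2. Probe sets whose mean log2 signal over the 4 arrays lay above the 40th percentile were tested, which left 13647 with a geometric mean signal above 24.8. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Differences are given as 35S::CBF2 minus wild type on the log2 scale with limma's standard error (SE), and folds are ratios of geometric means over the n = 2 arrays of each group. Where both arrays of the dimmer group lay below 14.5, the highest signal of 27 control probe sets for bacterial genes over all arrays, only a bound is given, the geometric mean of the brighter group over that floor. These are the bounds written as "at least". Few arrays limit the precision: 2 per group is the smallest number that still gives a spread.

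Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, on 1 probe set per gene (the brightest), for lists with at least 3 tested members. An estimated correlation and fry were run beside it. There were 18 lists: the CBF/DREB1 family, CBF-regulated cold genes, other cold-induced transcription regulators, sugar and proline metabolism, gibberellin metabolism and DELLA, dehydrins and LEA proteins, ABA-responsive genes, photosynthesis, flavonoids and anthocyanins, flowering time, circadian clock, heat shock proteins, expansins and XTH wall enzymes, cell cycle, defence and jasmonate, root markers, flower and seed markers, and commonly used reference genes. The groups, the test, the filter, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Named genes are the 12 largest rises and 10 largest falls among probe sets with 1 gene that passed the threshold without overlap between the groups, all measured members of the CBF-regulated cold genes and the CBF/DREB1 family, and up to 4 members of each other list with the smallest p.

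The alternatives were quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, an offset of 11.7 (the 25th percentile of all signals) before the log, eBayes without the trend or with robust estimation, the letter of the sample titles as a block, leaving out each array in turn, an adjusted p under 0.1, and a 2-fold difference in all 4 pairs of arrays. The planned search for the CBF binding motif in promoters needs a genome sequence, which was not used here, and was not run. CBF2 itself has no probe set in the annotation used here, so its signal is not reported. A probe set of CBF2 among those not listed would be counted with the rest, so the counts may include the transgene's own transcript.

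The procedure was tested on simulated data. Signals were drawn for the 13647 probe sets of the comparison of 35S::CBF2 with wild type, from the measured means and the fitted spread, and 200 of them were changed. limma recovered 31% of the 2-fold changes and 89% of the 4-fold changes, and 2.44% of its 123 calls were false. The simulated probe sets were independent of each other and followed the model that limma assumes, so these shares may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.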

Results

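CBF2 is a transcription factor of the AP2/ERF class that takes part in the cold response, and the series asks which transcripts respond when it is expressed from the 35S promoter in plants kept at 24 °C. RNA from 2 wild type and 2 35S::CBF2 samples of whole 10-day-old plants was measured, 1 array per sample. Median signals of gene probe sets were 42.1 and 41.6 on the wild type arrays and 42.4 and 39.6 on the 35S::CBF2 arrays. Log2 signals of the tested probe sets correlated at r = 0.966 between the wild type arrays and at 0.966 between the 35S::CBF2 arrays. Across groups this correlation lay between 0.922 and 0.940, and these are correlations across probe sets, which are not independent replicates.

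In 35S::CBF2 plants kept in the warm, transcripts of known cold-regulated genes were among the largest rises. COR15A, which encodes a chloroplast protein that protects membranes in the cold, had signals of 13.2 and 6.18 on the wild type arrays and of 8987 and 8018 on the 35S::CBF2 arrays, at least 586-fold higher (adjusted p = 1.15e-08). Its close relative COR15B rose from a geometric mean of 75.1 to 4508 (log2 difference 5.91 ± 0.17, SE, n = 2 per group). The dehydrin gene LTI30 rose 104-fold, from a geometric mean of 46.7 to 4839 (log2 difference 6.70 ± 0.16, adjusted p = 6.67e-09). COR47, a dehydrin gene that already had a signal of 1381 in wild type, rose 5.65-fold to 7809 (log2 difference 2.50 ± 0.15, adjusted p = 3.49e-06).

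Of the 18 CBF-regulated cold genes listed, 5 had a named probe set and were tested, and 4 of them rose. The remaining member, STZ, encodes a zinc finger protein and had a log2 difference of 0.92 ± 0.38 that did not pass (adjusted p = 0.310). Adjusted over the list alone, all 5 passed, with an adjusted p of at most 0.0336, that of STZ. As the largest of the 5, this value equals the unadjusted p of STZ, so it adds no support for that gene. Adjusted over all tested probe sets, STZ did not pass in any of the 13 alternatives in which it was tested. As a group the list was higher in 35S::CBF2, with a mean log2 difference of 5.18 and a median of 5.91 (limma camera, adjusted p = 8.84e-22). The call held with an estimated correlation (adjusted p = 0.0495) and with fry (adjusted p = 0.00138), which tests whether the genes move 1 way on balance. With signals below the floor raised to it, the mean was 5.04. The dehydrins and LEA proteins had 2 tested members, LTI30 and COR47, and both rose; both are also in the list of cold genes.

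**Figure D1:**
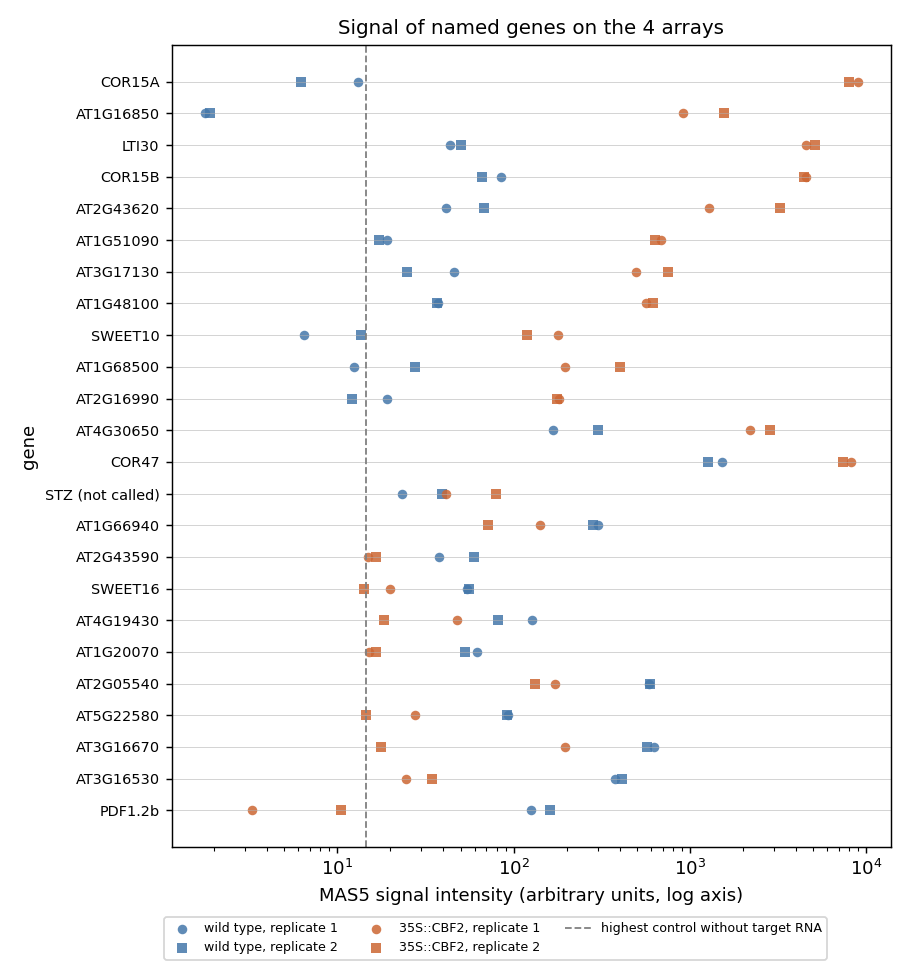
Signal intensity of the genes with the largest rises and falls and of the measured CBF-regulated cold genes, 1 point per array, on a log axis in arbitrary MAS5 units; the dashed line marks the floor of 14.5. COR15A lies below the floor on both wild type arrays and at 8987 and 8018 on the 35S::CBF2 arrays, and STZ did not pass the test.

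Named genes outside the list of cold genes rose as well. AT1G16850 had wild type signals of 1.77 and 1.90 and was at least 82.5-fold higher in 35S::CBF2 (adjusted p = 2.84e-08). AT2G43620, a member of the chitinase family, rose 38.3-fold (log2 difference 5.26 ± 0.37), with 61.0-fold without 35S::CBF2 replicate 1 and 24.0-fold without replicate 2. AT1G51090 rose 36.5-fold (5.19 ± 0.20). AT3G17130, of the invertase and pectin methylesterase inhibitor family, rose from 33.6 to 611 (log2 difference 4.19 ± 0.30), and AT1G48100, of the polygalacturonase family, rose 15.9-fold. SWEET10, a member of the SWEET sugar transporter family, was at least 10.1-fold higher (adjusted p = 2.21e-04). AT4G30650, of a family of small low-temperature and salt responsive proteins, rose 11.1-fold, from 225 to 2492. AT1G68500 rose 15.2-fold and AT2G16990 11.7-fold. In each of the genes named in this paragraph both 35S::CBF2 arrays lay above both wild type arrays, and each passed under every alternative in which it was tested.

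The largest falls among named genes were those of PDF1.2b, AT3G16530 and AT3G16670. PDF1.2b, which encodes a plant defensin, had signals of 125 and 162 in wild type and 3.28 and 10.5 in 35S::CBF2, at least 9.82-fold lower (adjusted p = 4.05e-04). The probe set of PDF1.2b is one that the array marks as shared between genes, so transcripts of related genes may contribute to its signal. The related defensin gene PDF1.2 was below the filter and not tested; its signals were 84.6 and 129 in wild type and 4.45 and 4.12 in 35S::CBF2, at least 7.21-fold lower. AT3G16530, which encodes a lectin-like protein, fell 13.6-fold (log2 difference -3.77 ± 0.22, adjusted p = 3.79e-06). AT5G22580 fell 4.60-fold, AT2G05540 3.91-fold, AT1G66940 2.88-fold and AT1G20070 3.60-fold. SWEET16, which encodes a vacuolar sugar transporter, fell 3.29-fold (adjusted p = 0.0172), and AT2G43590, of the chitinase family, fell 3.02-fold (adjusted p = 0.0413). AT4G19430 fell 3.43-fold (adjusted p = 0.0413). AT3G16670 had signals of 630 and 574 in wild type and a geometric mean of 58.7 in 35S::CBF2, where the arrays differed with an SD of 2.46 on the log2 scale (log2 difference -3.36 ± 0.78, adjusted p = 0.0418).

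Several of these falls depended on single arrays. The call of AT1G20070 was lost without wild type replicate 1 (adjusted p = 0.0762). That of SWEET16 was lost without wild type replicate 1 (0.0762), wild type replicate 2 (0.0963) or 35S::CBF2 replicate 2 (0.0702). That of AT2G43590 was lost without wild type replicate 2 (0.343), 35S::CBF2 replicate 1 (0.0726) or 35S::CBF2 replicate 2 (0.0857), and that of AT4G19430 without wild type replicate 1 (0.171) or 35S::CBF2 replicate 2 (0.141). Without 35S::CBF2 replicate 1 and without replicate 2, the fall of AT4G19430 was 5.52-fold and 2.13-fold, and that of AT3G16670 34.2-fold and 3.06-fold. The call of AT3G16670 was lost in 5 of 14 alternatives, and that of AT1G66940 without the intensity trend (0.0859). Over all alternatives the adjusted p ranged from 0.00712 to 0.0762 for AT1G20070, from 0.0108 to 0.0963 for SWEET16, from 0.0333 to 0.343 for AT2G43590, from 0.00121 to 0.171 for AT4G19430, from 1.98e-04 to 0.0859 for AT1G66940 and from 5.90e-08 to 0.593 for AT3G16670.

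Over the whole array, 458 of the 13647 tested probe sets passed the threshold, or 3.36%. Of these 288 were higher and 170 lower in 35S::CBF2. The median log2 difference was 1.46 among the higher and -1.14 among the lower. A difference of at least 4-fold was reached by 79 higher and 14 lower probe sets. Both groups were apart without overlap in all 458, which a choice by the difference between the groups favours, so it adds no support. Of all tested probe sets 41.7% were apart, where chance gives 33.3% for 2 arrays against 2. Of the 458, 209 carry exactly 1 gene, with 141 higher and 68 lower. Without 35S::CBF2 replicate 2 the count was 270, with 178 higher and 92 lower, and the lower count was 103 without wild type replicate 1 and 271 without 35S::CBF2 replicate 1. Without the intensity trend in eBayes 205 passed, 157 higher and 48 lower.

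**Figure D2:**
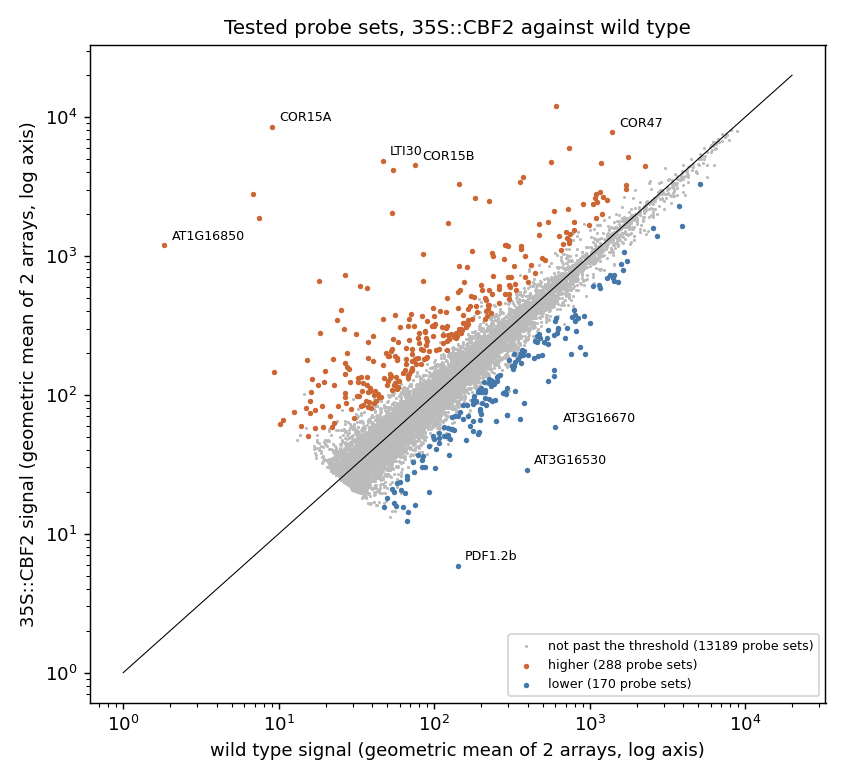
Geometric mean signal of each tested probe set in wild type (horizontal) and 35S::CBF2 (vertical), n = 2 arrays each, both axes logarithmic in arbitrary MAS5 units, with the line of equal signal. The 288 higher probe sets lie above the line and the 170 lower ones below it, with COR15A and AT1G16850 farthest above among the labelled genes.

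The tested genes of photosynthesis, gibberellin perception, root identity and common reference genes did not pass as groups, and 0 of the other 4 tested lists did (limma camera, adjusted p from 0.552 to 0.776). Coverage was low, with 4 of 26 listed photosynthesis genes tested and 3 of 20 for gibberellin metabolism and DELLA. For root markers it was 3 of 13 and for reference genes 3 of 9, so the lists as a whole stay largely untested. At an unadjusted p under 0.05, 0 of these 4 lists passed as well, with camera or with fry. The photosynthesis genes LHCB4.1, LHCB4.2, RCA and SBPASE had log2 differences between -0.12 and -0.03, and none passed. The gibberellin receptor genes had log2 differences of 0.61 (GID1B), 0.40 (GID1A) and -0.26 (GID1C), with 0 of 3 past the threshold. The root-expressed genes EXPA7, EXPA18 and PYK10 lay between -0.26 and 0.04. The reference genes PEX4, AT4G34270 and AT2G28390 lay between -0.02 and 0.14, and none of these passed. The expansin gene EXPA8 had a log2 difference of -1.08 ± 0.34 and did not pass (adjusted p = 0.147, and 0.00855 adjusted over the list alone, of which it is the only tested member); without 35S::CBF2 replicate 1 its adjusted p was 0.00317 and without wild type replicate 2 it was 0.0317, in a range of 0.00317 to 0.635 over all alternatives. ATSPS4F, DFR, GI and PRL, the only tested members of their lists, had log2 differences of -0.08, 0.39, 0.37 and -0.25 and did not pass. The signs of ATSPS4F, DFR and GI depended on single arrays: without 35S::CBF2 replicate 1 the values were 0.28, 0.80 and -0.25, and without 35S::CBF2 replicate 2 they were -0.44, -0.01 and 1.00. The list of heat shock proteins and that of defence and jasmonate genes had 0 tested members, and 4 lists had no named probe set: the CBF/DREB1 family, other cold-induced transcription regulators, ABA-responsive genes, and flower and seed markers.

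The 35S::CBF2 arrays were also compared with each other, since their titles carry different codes. Each was set against a different wild type array, replicate 1 against wild type replicate 2 and replicate 2 against wild type replicate 1. The log2 differences correlated across the tested probe sets at r = 0.540 (Spearman 0.289), at 0.486 with the wild type arrays exchanged, and at 0.130 over all gene probe sets with no filter. Among the 458 changed probe sets, 21 (4.59%) differed by at least 2-fold between the 35S::CBF2 arrays and 17 between the wild type arrays. Of all tested probe sets, 325 (2.38%) differed by that much between the 35S::CBF2 arrays and 292 (2.14%) between the wild type arrays. The calls favour a small spread within groups, so the counts among the 458 do not measure how well the arrays agree. COR15A, COR15B, LTI30 and COR47 were higher on both 35S::CBF2 arrays than on either wild type array.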

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

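The tests on the spike-ins and on scatter of unchanged probe sets were chosen after their results were seen, and the tests on scatter of changed ones and on the width of the log scale after related values were seen: of the 458 changed probe sets, 70.5% lay farther from wild type in 35S::CBF2 replicate 2 (95% exact binomial interval 66.1% to 74.7%). A stronger response was first taken to explain that share, and was dropped as an explanation because the share does not separate it from unequal noise of the arrays. The hybridisation spike-in controls, bacterial and phage sequences that the comparisons did not use, had 1.91 times the wild type mean on 35S::CBF2 replicate 2 and 0.664 times on 35S::CBF2 replicate 1 (geometric mean over 9 probe sets), against 0.986 and 1.01 on the wild type arrays. 35S::CBF2 replicate 2 was singled out because a signal outside the main measurement exceeded that of the wild type arrays.

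The array with the bright spike-ins was also the farther from wild type. On 35S::CBF2 replicate 2, 881 and 942 tested probe sets differed at least 2-fold from the wild type arrays, against 611 and 615 on replicate 1. A single scaling factor for the whole array is not enough as a cause of the bright spike-ins. These exceeded wild type by factors from 1.22 to 2.78, a ratio of 2.27. The wild type arrays gave a ratio of 1.13 and 35S::CBF2 replicate 1 gave 1.498. Saturation of the brightest spike-ins was not tested. The spike-ins do not show whether scaling moved the gene probe sets. Median signals of the gene probe sets were 39.6 on 35S::CBF2 replicate 2 and 42.4 on 35S::CBF2 replicate 1. Scatter of single probe sets goes with the probe sets that did not change, whose log2 distances from wild type had an SD of 0.428 in replicate 2 and 0.347 in replicate 1, a ratio of 1.23; there it cannot be told apart from a difference between the plants. For the changed ones scatter as the whole cause is argued against, by a small margin: of 299 probe sets called on the other 3 arrays, so that noise of replicate 2 did not enter the choice, 57.5% lay farther from wild type in replicate 2 (interval 51.7% to 63.2%, taking probe sets as independent). The filter for that choice was also taken on the other 3 arrays. Its number of calls therefore differs from the count without 35S::CBF2 replicate 2 given elsewhere, which kept the filter on all 4 arrays. A share of 75.3% among 4-fold changes, computed earlier, is not used as evidence, since replicate 2 entered the choice of those probe sets. A wider log scale of the whole array cannot be told apart from a stronger response: the SD of log2 signal of probe sets that did not change was 1.03 times larger in replicate 2, inside the 95% bootstrap interval of 1.02 to 1.103 for the slope of the 4-fold changes, a set chosen with both arrays, and no biological explanation was tested because the labels put both arrays in 1 group.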

How the results depend on the processing

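The alternatives without probe sets marked as shared between genes and with a floor before the log were chosen after seeing the data; the others were planned. The number of changed probe sets (458 as reported) was 205 without the intensity trend, 229 with the 2-fold criterion in all 4 pairs of arrays, 661 with the title letter as a block, 619 at an adjusted p under 0.1, and 270 to 605 when each array was left out in turn, with the lone array assumed to vary like the other group. The higher ones (288) were 157 without the trend, 171 with the 2-fold criterion, 380 with the block, 360 at an adjusted p under 0.1, and 178 to 334 with an array left out. The lower ones (170) were 96 with no filter, 48 without the trend, 281 with the title letter as a block, 259 at an adjusted p under 0.1, 58 with the 2-fold criterion, and 92 to 271 with an array left out. The cause was not tested. Higher probe sets made up 62.9% of the calls, 64.3% after quantile normalization, 65.7% after centring on medians, 76.6% without the trend, 57.5% with the title letter as a block, and 55.2% (without 35S::CBF2 replicate 1) to 74.9% (without wild type replicate 1) with an array left out. The calls also among the 458 were 197 of 205 without the trend, 458 of 661 with the block, 322 of 411 and 313 of 372 without wild type replicates 1 and 2, and 389 of 605 and 257 of 270 without 35S::CBF2 replicates 1 and 2. The log2 differences of the 35S::CBF2 arrays from different wild type arrays correlated at 0.130 with no filter, which adds dim probe sets, against 0.540. The shift of the CBF-regulated cold genes kept its direction and its call in all 17 alternatives, with means from 4.79 to 6.25. The mean of 6.25 came from the filter at the 60th percentile, which dropped STZ, so it is not a larger shift of the same genes. That filter also left the lists of gibberellin genes and root markers with too few members to be tested. None of the other 4 preset lists passed in any alternative in which it was tested. For the genes named by the fixed rule, 549 comparisons kept the call, 22 lost it and 2 (EXPA8) gained it, and no called gene changed sign. Replicate numbers could not pair the arrays, since the groups share only 1 in the labels. The title letters, whose meaning the labels do not give, were used as the block instead, and arrays of the same letter had deviations correlated at 0.07 across probe sets. The motif alternatives and those for the signal of CBF2 were not run. Signal over background limits the folds of 6 higher and 1 lower probe sets to bounds.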

Other observations

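The gene families, the genes named here outside the fixed rule, and the tests on scaling, background and neighbouring genes were chosen after values had been seen. Members of the SWEET sugar transporter family moved in both directions: of 8 tested genes, SWEET10, SWEET13 (log2 difference 1.87) and SWEET1 (1.35) rose and SWEET16 and SWEET11 (-0.97) fell. As a set they did not pass in 1 direction (camera, adjusted p = 0.946), while fry's test for change in either direction passed over the 14 families tested (adjusted p = 0.0274). The signs of these 5 genes held under each scaling alternative. That is a weak check, since the median log2 difference of tested probe sets moved only from -0.036 to -0.027 (quantile normalization) and -0.006 (centring). Both falls were less stable than that: the call of SWEET16 was lost in 4 of the 13 alternatives in which it was tested. The call of SWEET11 was lost without wild type replicate 2 or 35S::CBF2 replicate 2 (log2 difference -0.82 in both). Its adjusted p ranged from 0.00143 to 0.102 over the alternatives (limma). Fry's test for either direction also passed for the UDP-glycosyltransferases (adjusted p = 0.0147, 2 of 22 tested genes called), the expansins (0.0268, 2 of 12) and the tetraspanins (0.0353, 1 of 6). That test asks whether any members differ between the groups, without a comparison with other genes. The called members alone can make it pass, and the families were chosen after values had been seen. It therefore adds no support beyond those calls and does not show that a family responded as a whole. Of the 2 glycosyltransferase calls, that of UGT74D1 (limma, adjusted p = 0.0375) was lost in 4 of 14 alternatives. None of these 4 families passed in 1 direction, with camera (adjusted p from 0.866 to 0.946), with an estimated correlation (adjusted p = 0.965) or with fry's directional test (0.109 to 0.870). The serine carboxypeptidase-like family, with 15 tested genes and 0 called, was lower but missed the threshold (camera, adjusted p = 0.0528). It passed after quantile normalization (0.0439), after centring (0.0387) and without the trend (0.0411). It did not pass with no filter (0.227), an estimated correlation (0.965) or fry (0.376). The glycosyltransferase gene UGT72B3 rose 8.07-fold and the expansin-like gene EXLA2 4.36-fold, while the expansin-like gene EXLB1 fell (log2 difference -1.20), a call lost without wild type replicate 2 (adjusted p = 0.0889) or 35S::CBF2 replicate 2 (0.0744; range 0.00507 to 0.0889). The beta-glucosidase gene BGLU25 rose 3.61-fold and the tetraspanin gene TET3 2.53-fold.

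Chloroplast-encoded genes gave a result that depended on a single array. Of 68 tested genes, rbcL, which encodes the large subunit of Rubisco, rose 2.11-fold (adjusted p = 0.00574, and 0.0550 without the intensity trend, in a range of 0.00191 to 0.0550) and 67 did not pass. As a set they were higher in 35S::CBF2 by a mean log2 difference of 0.36 (camera, adjusted p = 3.13e-06), but with an estimated correlation the adjusted p was 0.965 and with fry 0.859. Their mean relative to the wild type average was 0.39 on wild type replicate 1, -0.39 on wild type replicate 2, and 0.38 and 0.34 on the 35S::CBF2 arrays. Without wild type replicate 2 the mean difference was -0.03 (adjusted p = 0.931), and without wild type replicate 1 it was 0.75.

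More probe sets were higher than lower in 35S::CBF2, 62.9% of the calls. Scaling by the authors stays open as the cause. With each array centred on its median the share was 65.7% (95% exact binomial interval 61.1% to 70.2%, taking probe sets as independent). The medians were already close (42.1 and 41.6 in wild type, 42.4 and 39.6 in 35S::CBF2). Centring could therefore change little, and it tests only unequal medians. Falls of dim probe sets hidden by background stay open. Among 222 changed probe sets above the 80th percentile of wild type signal, where a fall can be seen, 44.6% were higher (37.9% to 51.4%), which the rule written for the test counted as fitting this explanation. After the result was seen it was relabelled as undecided, because choosing by wild type signal favours falls. With the 80th percentile taken over all 4 arrays, a choice that lets in rises from a dim wild type signal, 62.9% of 240 were higher. Among all calls, the share was 55.2% without 35S::CBF2 replicate 1 and 74.9% without wild type replicate 1. The expression of CBF2 itself stays open as an explanation and was not tested, since the promoter motif search was not run. With 4 arrays there are 3 splits of 2 against 2, too few for a share under 0.05. The real split called 458 probe sets and each of the others called 0 (limma, 233 and 396 at an unadjusted p under 0.05, against 1781). Both other splits mix wild type and 35S::CBF2 arrays in each group. The difference between wild type and 35S::CBF2 then counts as spread and lowers the calls, so these counts do not measure chance.

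Some genes that rose together lie next to each other on the chromosomes. Among 2099 pairs of neighbouring genes with both members tested, 5 pairs rose together and 0 moved in opposite directions: COR15A with COR15B, SWEET10 with SWEET13, AT1G16840 with AT1G16850, AT1G76580 with AT1G76590, and AT5G62350 with AT5G62360. Chance placement is argued against, since a share of 0.00320 of 10000 random placements of the 206 changed genes gave as many pairs, with a median of 1. Probe sets marked as shared between genes are argued against as well, since none of the probe sets in these 5 pairs is so marked. Leaving the marked ones out therefore had to keep the same 5 pairs. The share without them, 0.00310, is not separate evidence. Cross-hybridisation between similar sequences that the array does not mark, and shared regulation of neighbours, may each contribute and stay open, since probe sequences were not used here; the call of AT5G62360 (adjusted p = 0.0212) ranged from 2.01e-05 to 0.138 over the alternatives, and its fold was 2.38 without 35S::CBF2 replicate 1 and 6.32 without replicate 2.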
